A study of Mus musculus with 16 samples.

How the data were processed

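Genomic DNA from the tails of 8 C57BL/6 mice of 1 family was compared with DNA of 1 reference male by two-colour array comparative genomic hybridisation, in which DNA of a test animal and of a reference, labelled with different dyes, compete for the same probes. Per the labels, the family consists of a male parent, a female parent and 6 progeny numbered 1 to 6. Each mouse was hybridised on 2 arrays with exchanged dyes, giving 16 arrays, and the reference male was on all of them. Per the file headers, positions are on the mouse build mm9. Images were quantified with Feature Extraction 10.7.1.1, per the file headers.

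Per the file headers, the processed signals are intensity values after background subtraction, spatial detrending and dye normalisation within the array. The deposited scanner files also hold a log10 ratio of Cy5 over Cy3. The deposited value table of the series holds log2 ratios. Set against the scanner values, that table ran as reference over mouse in both dye orientations and had not been centred, with column medians between -0.01 and 0.02. How its missing values were chosen is not given in the sources used here. Here all ratios are given as mouse over reference, the opposite direction.

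The starting values were log2 ratios of the processed signals. Control features were left out, as were features that the scanner software marked as outliers. Repeated features of a probe were averaged, and each array was centred on its autosomal median. The 966371 non-control features gave 950713 probes, of which 950622 lay on the 19 autosomes, 68 on the X chromosome and 23 on the Y chromosome. The median distance between autosomal probes was 2053 bp. No loess or quantile normalisation was applied in the main setting. The direction of the ratio followed the dyes in the labels. The mean of a mouse's dye-swapped arrays counted as 1 replicate. Whether the DNA of a mouse was extracted once or separately for each array is not given in the sources used here. The number of arrays limits the precision.

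Copy number calls were made per mouse with an interval score, the sum of log2 ratios divided by the robust probe SD and by the square root of the number of probes. A call needed a score of at least 6 in size, at least 3 probes, a mean log2 ratio of at least 0.25 in size, and a score of at least 3 with the same sign in each dye orientation. Overlapping calls of different mice were joined into a region with the limits of the highest-scoring call. A background came from the same search after turning the sign of 1 orientation, which removes DNA differences and keeps noise. Dye bias, which the swap cancels, adds up in this background, so it is no clean estimate of false calls. Over a region, a mouse was given a gain or loss at 0.25 in size if each orientation reached its own minimum, no change below 0.15, and was otherwise undetermined. Errors on a region's mean are standard errors over its probes within 1 mouse. They are not errors between animals.

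Means of 10 consecutive autosomal probes, 95054 windows, were fitted with limma 3.58.1 in R 4.3.3 with the progeny and each parent as separate groups, so that the spread came from the 6 progeny. limma moderated the spread of each window towards that of all windows. Windows passed at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 0.25 on the log2 scale. The number of calls per mouse was compared between progeny and parents with an exact two-sided permutation test over all 28 splits. Scan days formed 4 sessions. Both parents were scanned in the first, progeny 1 and 2 in the second, progeny 3 and 4 in the third, and progeny 5 and 6 in the fourth. The main fit held no session term, and the session was fitted as a random block in an alternative only. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

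The search was tested on simulated steps added to the sign-turned data of all 8 mice. It recovered 86.5% of 200 losses of -0.8 over 3 probes and all 200 over 5 probes. Of gains of 0.5 it recovered 9.0% over 3 probes, 44.5% over 5, 96.0% over 10 and 100% over 30. The orientations of a mouse correlated negatively (r between -0.41 and -0.07), so turning the sign of 1 makes their mean noisier. These shares therefore come from noisier values than those searched, and recovery in the data itself can be higher. The window fit was tested on normal values simulated for 95054 windows, with 1 robust spread per mouse and each difference added to all progeny. It recovered 84.5% of 200 differences of 0.3 between progeny and parents, and 99.5% of such differences from the reference. Of differences of 0.5 it recovered all 200 in both. Spreads that vary between windows, faults of an array and changes in only some progeny were not simulated, so these shares do not cover them.

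Regions named in the text were the 12 with the highest score and the 12 highest-scoring regions in progeny and neither parent, which overlap in 2 regions, and for limma up to 10 windows with the largest change. Regions named outside this rule are said to be so. This rule, the tests and most alternatives were fixed before the data were examined. The alternatives covered background correction, loess, the value table, a filter on dim probes, genomic waves, single dye orientations, thresholds, window sizes and each progeny left out. After seeing the data, a score of at least 15, leaving out the male parent's Cy5 array, leaving out array blocks rich in extreme features, and keeping only calls whose mean stays at least 0.25 in size without their most extreme probe were added. For the blocks, each array was divided into 1600 blocks of 27 rows by 23 columns, and a block was left out where over 3% of its features differed from the array median by over 1 on the log2 scale. The normexp alternative used median signals, the scanner columns used here, in place of means.

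The files pair probes with positions only, and no annotation of that build was used here, so no genes are named and the planned test of gene lists in called regions was not run.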

Results

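DNA copy number was surveyed across the autosomes of 1 mouse family by array comparative genomic hybridisation with probes spaced at a median of 2053 bp. The series title describes males exposed to gamma rays at 0.05 mGy per day for 400 days, and asks whether copy number changes appear in their progeny. The design text calls the male parent of this family non-irradiated in 1 place, so its exposure is not settled by the labels. No second family was analysed here, so no comparison by exposure was possible. The data were 16 arrays of tail DNA from a male parent, a female parent and 6 progeny, each mouse on 2 dye-swapped arrays against the same reference male of the colony. Values are log2 ratios of mouse over reference, and each mouse is a single animal.

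The X probes separated the mice. Over 68 probes the mean log2 ratio was 0.89 in the female parent, 0.84 in progeny 4, 0.83 in progeny 5 and 0.81 in progeny 6. In the male parent and progeny 1, 2 and 3 it lay between -0.02 and 0.03. The labels do not give the sex of the progeny. Over 23 Y probes the median was -1.82 in the female parent, -1.54 in progeny 4, -0.89 in progeny 5 and -0.86 in progeny 6, and between -0.11 and -0.03 in the other mice. By both chromosomes, progeny 4, 5 and 6 lay with the female parent and progeny 1, 2 and 3 with the male parent. This is the pattern of females and males against a male reference. The X median of the female parent was 0.94 on its Cy3 array and 0.85 on its Cy5 array.

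The arrays differed in quality. The robust SD of single probes after averaging the dye swap was 0.09 in progeny 5, 0.10 in progeny 6, between 0.13 and 0.16 in the female parent and progeny 1 to 4, and 0.18 in the male parent. Within a mouse, the orientations correlated at an r between -0.41 and -0.07 across probes, which are not independent replicates. On the Cy5 array of the male parent, 2.00% of features differed from the array median by over 1 on the log2 scale, and 83.6% of these lay in 5% of the array's blocks. The corresponding share of features was between 0.04% and 1.02% on the other 15 arrays. The Cy5 array of progeny 4 was the next highest, with 53.2% of its extreme features in 5% of the blocks.

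**Figure D1:**
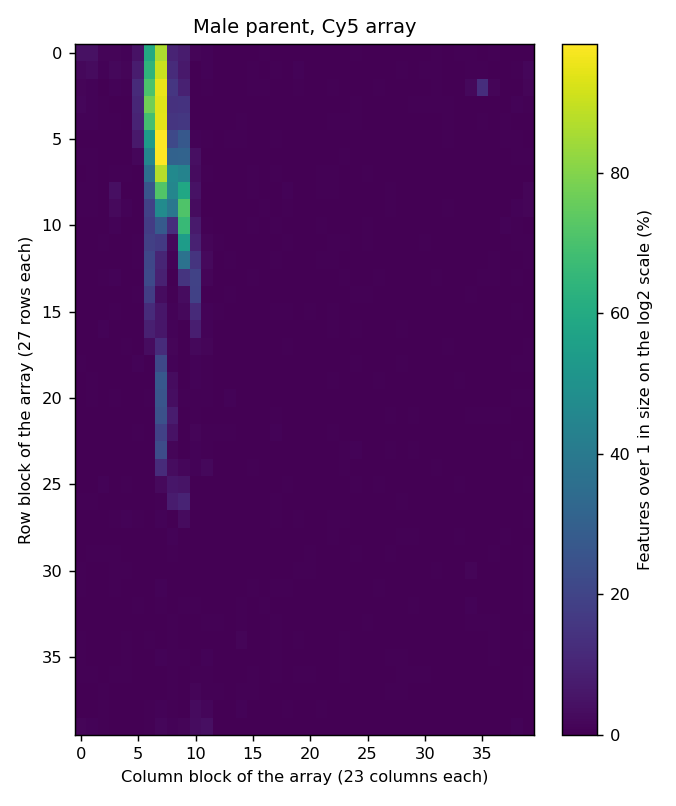
Share of features, in percent, that differed from the array median by over 1 on the log2 scale, in each of 1600 blocks of the male parent's Cy5 array, laid out by row and column of the array. The extreme features form a streak along the left side, reaching 98.4% in a block, while the median block held 0.27%.

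The first question was where any mouse of the family differed in copy number from the reference. The strongest difference was a gain on chromosome 4, from 101110482 to 101270535, over 74 probes and 160054 bp, carried by the male parent and 4 of the 6 progeny. A weaker gain on chromosome 8, from 102148548 to 102253497, over 38 probes, was carried by the female parent and progeny 4, 5 and 6, the mice with the higher X ratio. A loss on chromosome 13, from 65468928 to 66964615, over 25 probes, was seen in progeny 1 and in neither parent. A loss over 4 probes on chromosome 3, from 25417435 to 25444229, was carried by the female parent and progeny 4, 5 and 6. These 4 regions were among the 12 with the highest score.

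In all, 747 calls fell into 603 regions, 146 gains and 457 losses. The sign-turned background held 617 regions, so the number of regions as such did not exceed the background. The score separated them. The highest score was 49.2 in the data and 14.0 in the background, and 16 regions scored above that background value. Of the 603 regions, 370 had 3 probes, and 114 of these kept a mean of at least 0.25 in size without their most extreme probe. Of all 603 regions, 211 did. With array blocks rich in extreme features left out, 359 regions were called against a background of 252. Losses made up 75.8% of regions, and 98.4% with normexp background correction, which gave 8 gains and 499 losses against a background of 86 regions. From the mice's Cy3 arrays alone, losses made up 29.5%, from the Cy5 arrays alone 94.0%, and with probes well above background 87.1%. The Cy5 arrays alone gave 7678 regions, with a difference in mean calls of progeny minus parents of -2725. Their share of losses therefore leans on the parents, and the male parent's Cy5 array held the most extreme features.

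The gain on chromosome 4 had a mean log2 ratio of 0.54 ± 0.03 (SE over 74 probes) in the male parent, 0.52 ± 0.02 in progeny 2, 0.53 ± 0.02 in progeny 3, 0.52 ± 0.02 in progeny 4 and 0.52 ± 0.01 in progeny 5. It was 0.00 ± 0.01 in the female parent, 0.01 ± 0.02 in progeny 1 and 0.00 ± 0.01 in progeny 6. The carriers differed from each other by less than 1 SE of the male parent's mean, and each lay over 10 SE above the non-carriers. The gain on chromosome 8 was 0.26 in the female parent, 0.33 in progeny 4, 0.29 in progeny 5 and 0.29 in progeny 6, and between -0.05 and 0.04 in the other mice.

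**Figure D2:**
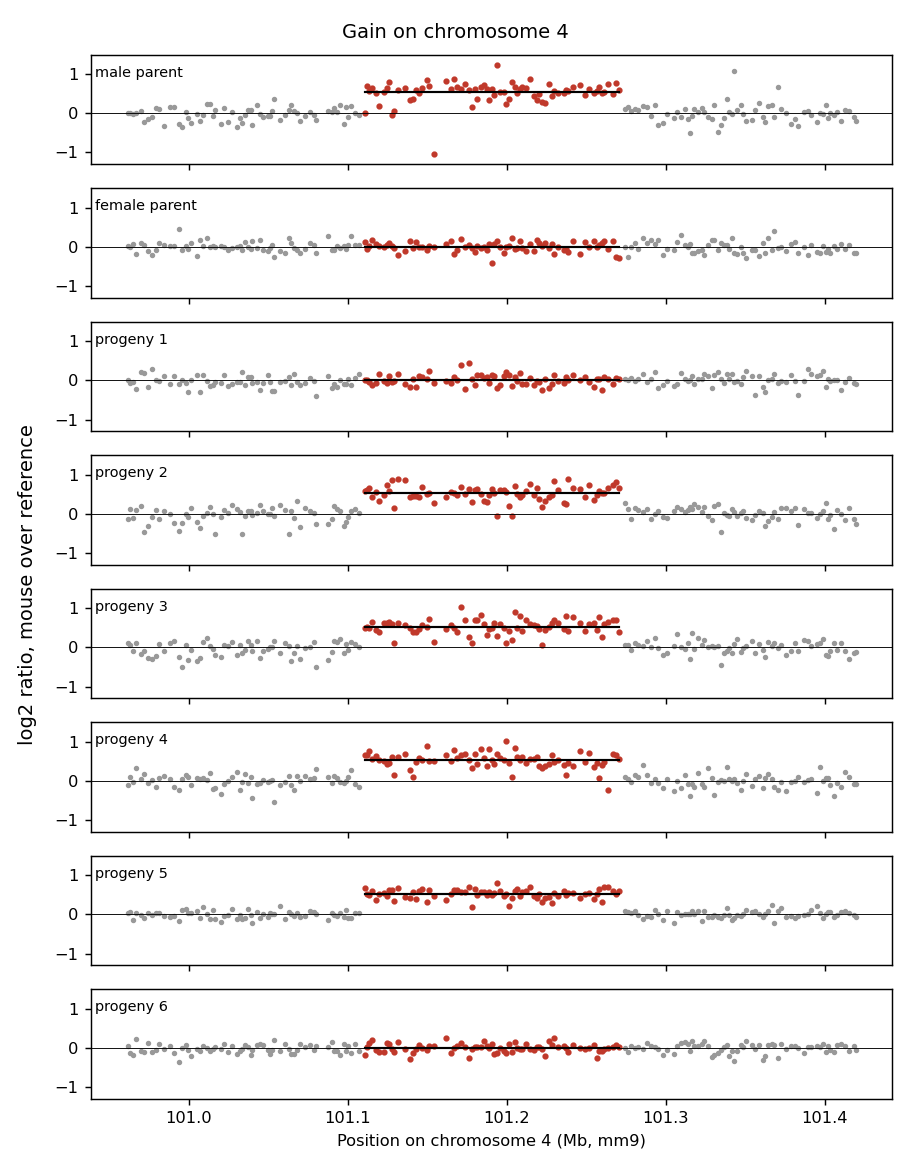
Log2 ratio of mouse over reference for each probe (points) against the position on chromosome 4 in Mb, 1 panel per mouse, with the probes of the called region in red and their mean as a black line. The line lies at 0.52 to 0.54 in the male parent and progeny 2, 3, 4 and 5, and at 0.00 to 0.01 in the other mice.

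The second question was which regions were shared between a parent and progeny. There were 103 such regions against 240 in the background. Sharing exceeded the background in 2 settings only. With normexp background correction there were 60 against 14, and at a score of at least 15, chosen after seeing the data, 11 against 0. In every other alternative with a background, sharing lay below it. A dye bias common to several mice would add up in this background as shared regions, so a count below it does not show that sharing is absent. For example, there were 113 against 132 with loess, 96 against 244 with the value table and 56 against 67 at a score of at least 8. The sets of carriers were uneven. A loss in exactly the female parent and progeny 4, 5 and 6, the mice with the higher X ratio, occurred at 34 regions on 14 chromosomes and at 0 in the background. Of these 34 losses, 32 covered 3 probes, and 29 did not keep a mean of 0.25 in size without their most extreme probe. In 1 of them, on chromosome 11 from 59712080, the male parent had a gain of 0.25. On chromosome 6, from 104241394 to 104246570, the means were -1.21 in the female parent, -1.39 in progeny 4, -1.29 in progeny 5 and -1.49 in progeny 6. There, 1 probe of 3 lay at -4.19 in progeny 6 and the others had a mean of -0.14. The losses on chromosome 7 from 141015947 to 141019267, on chromosome 3 from 132546474 to 132549490 and on chromosome 14 from 65230870 to 65234865 likewise had means between -0.07 and -0.05 without their most extreme probe in the top-scoring mouse. On chromosome 16, from 40847733 to 40851595, that mean was -0.29. The loss on chromosome 3 from 25417435 fell in all 4 mice, with means of -1.60, -1.50, -1.31 and -1.38 in the female parent and progeny 4, 5 and 6, and kept a mean of -1.07 in progeny 5 without its most extreme probe. A loss on chromosome 14 over 13 probes, from 61798066 to 61819370, had the same carriers and kept a mean of -0.34. It lies outside the naming rule and was chosen after its values were seen. The losses on chromosome 10 from 102871045 to 102877893 and on chromosome 3 from 95374904 to 95377628 were carried by the female parent and progeny 5 and 6. The first was -1.75 on the Cy3 array and -0.38 on the Cy5 array of progeny 6. The second had a mean of 0.03 in progeny 6 without its most extreme probe.

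**Figure D3:**
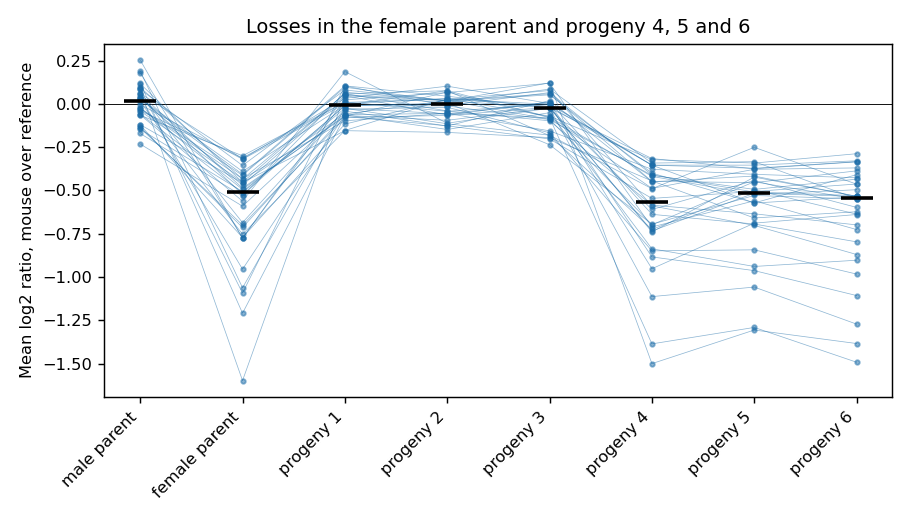
Mean log2 ratio of mouse over reference in each of the 34 losses carried by exactly the female parent and progeny 4, 5 and 6 (points joined by region), for all 8 mice, with the median over regions as a black bar. The medians are -0.51 in the female parent, -0.57 in progeny 4, -0.51 in progeny 5 and -0.54 in progeny 6, and between -0.02 and 0.02 in the other mice.

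The third question, the one the series title raises, was which regions appeared in progeny and in neither parent. The clearest was the loss on chromosome 13 in progeny 1, with a mean log2 ratio of -0.44 ± 0.04 (SE over 25 probes). It was -0.41 on the Cy5 array and -0.48 on the Cy3 array, all 25 probes had a mean below 0, and the mean stayed at -0.42 without the most extreme probe. The parents and the other 5 progeny lay between -0.03 and 0.04. Probes were sparse there, 25 over 1495688 bp where the mean spacing would give 589, with a gap of 404836 bp between neighbours. The mean was -0.48 over the 14 probes before the gap and -0.39 over the 11 after it. The 50 probes on either side of the region averaged 0.01 and -0.04.

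**Figure D4:**
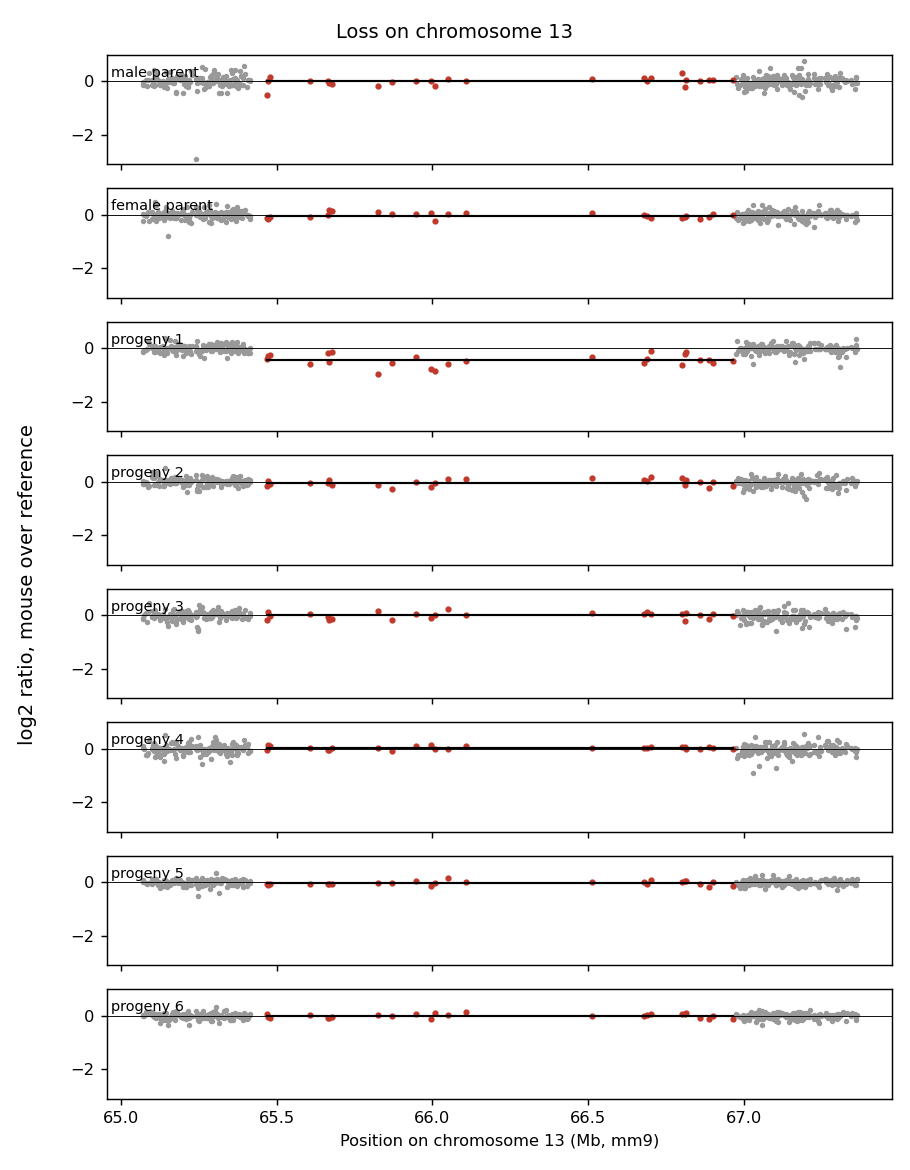
Log2 ratio of mouse over reference for each probe (points) against the position on chromosome 13 in Mb, 1 panel per mouse, with the 25 probes of the called region in red and their mean as a black line. The line lies at -0.44 in progeny 1 and between -0.03 and 0.04 in the other mice.

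Altogether 144 regions had a gain or loss in at least 1 progeny and no change in both parents, against 68 in the background. With at least 5 probes there were 100 against 50, and with at least 10 probes 31 against 31. Progeny 1 to 6 carried 31, 33, 21, 48, 28 and 28 of the 144, against 21, 14, 12, 47, 6 and 9 in the background. A dye bias shared with the parents would lower the background count, so the contrast is no clean excess. Of the 144, 11 were losses in exactly progeny 5 and 6, against 1 in the background. Over all 24 losses with these carriers, the median was -0.13 in the female parent, -0.19 in progeny 4, and between -0.07 and 0.04 in the other 4 mice. Only 2 of the 144 scored above the highest background score, and 91 covered 3 probes. Besides the chromosome 13 region, the second was a loss on chromosome 14 from 109499039 to 109502316 in progeny 5 and 6, whose mean in progeny 6 changed from -0.91 to -0.05 without its most extreme probe. Among the 12 highest-scoring regions of this kind, the loss on chromosome 5 from 126312454 to 126329901 was the only other one that kept 0.25 in size without its most extreme probe. It covered 7 probes, with means of -0.31 in progeny 4, -0.35 in progeny 5 and -0.33 in progeny 6, and was -0.14 in the female parent. The losses on chromosome 15 from 51633722, chromosome 9 from 95912888 and chromosome 7 from 16941129 were called in progeny 5 and 6, and that on chromosome 1 from 106041489 in progeny 5, each over 3 probes and with a mean no lower than -0.18 without the most extreme probe. For losses on chromosome 4 from 132275568 and from 96907811, carried by progeny 4, on chromosome 5 from 151743121, carried by progeny 1 and 2, and on chromosome 9 from 81662627, carried by progeny 1, 2 and 3, that mean lay between -0.23 and -0.13 in the top-scoring mouse. They covered 3 probes each, except that from 96907811, which covered 5. A gain over 9 probes on chromosome 6 from 36565897 in progeny 1 was 0.71 on the Cy5 array and 0.24 on the Cy3 array, and its mean was 0.18 without the most extreme probe. The number of such regions fell to 56 with normexp background correction, to 43 with probes well above background, and to 46 with only calls whose mean stayed at least 0.25 in size without their most extreme probe, against 12, 19 and 49 in the respective backgrounds.

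Progeny did not hold more calls than parents by the planned test. There were 204 calls in the male parent, 77 in the female parent, and 60, 64, 39, 111, 92 and 100 in progeny 1 to 6. The progeny mean was lower than that of the parents (difference -62.8, exact two-sided permutation p = 0.143, 28 splits). With array blocks rich in extreme features left out, the male parent had 19 calls and the progeny mean was 21.5 higher (exact two-sided permutation p = 0.393). Background calls numbered 316 in the male parent and 158 in progeny 4, but 15 in progeny 5 and 19 in progeny 6.

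**Figure D5:**
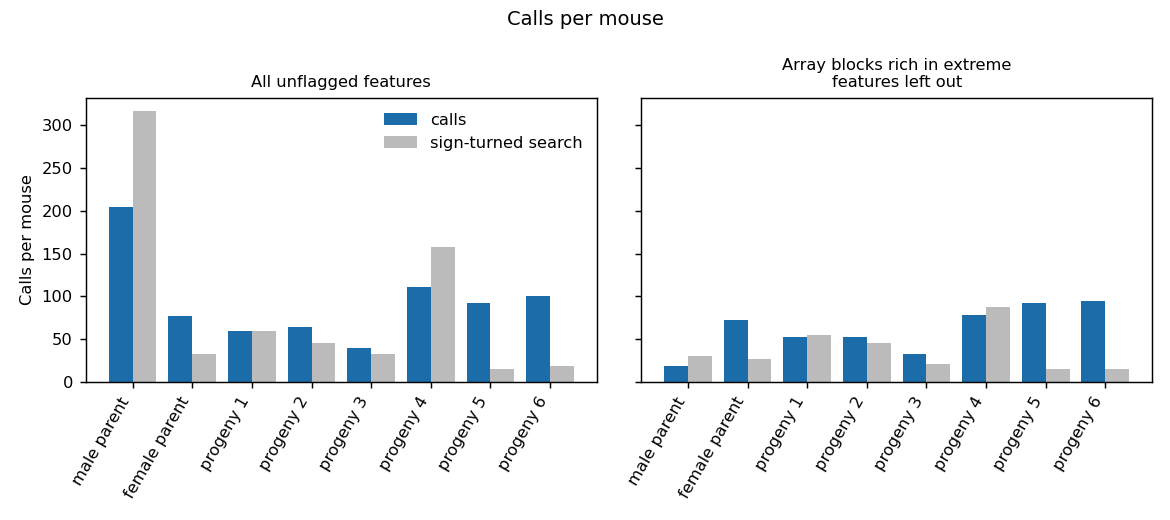
Number of calls per mouse (blue bars) and number from the sign-turned search (grey bars), with all features not marked as outliers on the left and with array blocks rich in extreme features left out on the right. The male parent has 204 calls on the left and 19 on the right, and progeny 5 has 92 in both.

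In windows of 10 probes, progeny were higher than the mean of the parents in 42 and lower in 1 of 95054 (limma, adjusted p under 0.05 and a difference of at least 0.25). The window with the largest difference, on chromosome 11 from 78549319 to 78572057, was 0.33 ± 0.04 (SE from limma, moderated across windows) higher in progeny with an adjusted p of 0.000183. There the male parent lay at -0.66, the female parent at 0.06, and the 6 progeny between -0.01 and 0.09. The windows on chromosome 5 from 98758944, chromosome 17 from 55178875 and chromosome 3 from 154596057 followed, with differences of 0.32, 0.32 and 0.31 and male parent values of -0.54, -0.47 and -0.62. In the 10 windows with the largest difference, the male parent lay between -0.66 and -0.47 and the female parent between -0.11 and 0.06. Over the 42 windows the median of the male parent was -0.95 on its Cy5 array and -0.03 on its Cy3 array. With array blocks rich in extreme features left out, limma called 0 windows, with 7656 at an unadjusted p under 0.05. It also called 0, with 8916 at an unadjusted p under 0.05, when the parents formed 1 group so that their own spread counted. All parent arrays were scanned in a session without progeny, and with the session as a random block 43 windows passed. Because no session held both parents and progeny, the block cannot separate the session from this contrast.

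Against the reference mouse, progeny differed in 6 windows, all higher and all within the chromosome 4 gain. The largest mean was 0.40 ± 0.06 (SE from limma, moderated across windows; n = 6, adjusted p = 0.0144), from 101166843 to 101185352, with 4 of 6 progeny between 0.52 and 0.61. Progeny 1 and 6 lay at 0.10 and 0.01 there. The SE and p lean on the spread of all windows, so they do not measure the spread among these 6 animals. The reference is a single male, so in general a difference from it can belong to either side of the ratio. For the chromosome 4 gain, a change in the reference alone is argued against, because every mouse would show it. The female parent, progeny 1 and progeny 6 lay at 0.00 ± 0.01, 0.01 ± 0.02 and 0.00 ± 0.01 over that region (SE over 74 probes). Without progeny 2 or progeny 3 the count was 0, with 10767 and 10616 windows at an unadjusted p under 0.05, and without progeny 4 or progeny 5 it was 1. It was also 0 with the parents as 1 group, with 10365 windows at an unadjusted p under 0.05.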

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

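All tests weighed in this part were chosen after the values had been seen.

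Among 28 values compared across the 6 progeny, 3 had a mouse far from the other 5. Chance would give about 1.4 among values not chosen for a difference, but all 3 are regions named because of a call in progeny and neither parent, so that number does not apply to them. The first was the chromosome 13 loss, at -0.44 in progeny 1. The second was the chromosome 6 gain from 36565897, at 0.475 in progeny 1 with the next progeny at 0.04; without array blocks rich in extreme features it was 0.18. The third was the chromosome 4 loss from 96907811, at -0.71 in progeny 4 with the next progeny at -0.07; without those blocks it was -0.14.

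For the chromosome 13 loss, a fault of a single array was weighed by calling on each array of progeny 1 alone. Called on the Cy5 array, the loss averaged -0.334 on the Cy3 array, and called on the Cy3 array, -0.40 on the Cy5 array. The other 7 losses of at least 10 probes called on the Cy5 array alone averaged no lower than -0.05 on the Cy3 array. The chromosome 13 region had been picked by a search that required a score of at least 3 on each array. The 7 losses had not, so the contrast with them cannot decide whether a single array was at fault. The 29 features of the region lay in 29 different array blocks. On either array of progeny 1, 0 of them lay in blocks rich in extreme features. Noise of the search reached a score of 13.96 at most in the sign-turned data, below the 17.0 of this region. A variant carried by both parents and the reference could still give it by segregation, because the other 7 mice differed from 0 by at most 0.035 and the copy number of the reference is unknown. Under it 1 in 2 progeny would differ on average, and 1 of 6 did, which is too few animals to decide. A new change in this animal stays open as a hypothesis, and no biological explanation, exposure of the father included, could be tested in 1 family. The mean of -0.44 was smaller in size than the X means of 0.81 to 0.89 in the female parent and progeny 4, 5 and 6. Which copy numbers it reflects was not tested.

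The male parent's low values may come from a damaged area of its Cy5 array. Leaving out array blocks rich in extreme features brought the windows that differ between progeny and parents from 43 to 0 (limma, 7656 at an unadjusted p under 0.05) and the male parent's calls from 204 to 19. A copy number change in the DNA of the male parent is argued against by its Cy3 array, whose median over the 42 windows was -0.031 where that of the Cy5 array was -0.95.

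The 34 losses in exactly the female parent and progeny 4, 5 and 6 form a pattern across chromosomes. Independent inheritance from the female parent would put this set on about 0.25 of 16 chromosomes, counting 1 region each, and it was found on 13 (one-sided binomial p = 1.77e-21). The set was chosen from these same losses, where it was the most frequent, so this p is not that of a set fixed in advance. Of the 34 losses, 29 did not keep a mean of 0.25 in size without their most extreme probe. Noise of the search gave 0 losses with this set. The set equals the mice with the higher X ratio, and 34 losses stand against at most 1 in any of the other 69 sets of 4 mice, which is consistent with probes that also bind sequence copies on the Y chromosome of the male reference. Such copies cannot give the chromosome 8 gain, which has the same carriers, and no genome was searched for them, so this remains a hypothesis.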

How the results depend on the processing

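A score of at least 15, the male parent without its Cy5 array, array blocks rich in extreme features left out, and a filter that keeps only calls whose mean stays at least 0.25 in size without their most extreme probe (the probe filter) were chosen after seeing the data. The cause of the shifts was not tested except where fewer probes, arrays or calls enter by construction. The number of regions (603) became 263 with probes well above background, 7678 from Cy5 arrays alone, 190 at a score of 8, 359 and 137 with at least 5 and 10 probes, 370 at a mean log2 of 0.5, 5317 with no requirement on single orientations, 13 at a score of 15, 359 without the rich blocks and 219 with the probe filter. Regions in progeny and neither parent (144) became 56 with normexp, 43 with probes well above background, 451 from Cy5 and 95 from Cy3 arrays alone, 28 at a score of 8, 31 with at least 10 probes, 68 at a mean log2 of 0.5, 493 with no requirement on single orientations, 2 at a score of 15 and 46 with the probe filter. Regions in a parent and at least 1 progeny (103) became 60 with normexp, 47 with probes well above background, 2454 from Cy5 and 310 from Cy3 arrays alone, 56 at a score of 8, 36 and 8 with at least 5 and 10 probes, 195 with no requirement on single orientations, 11 at a score of 15 and 34 with the probe filter. Leaving out each progeny in turn gave 521 to 576 regions, 106 to 131 in progeny and neither parent, and 86 to 99 in a parent and progeny. The difference in calls between progeny and parents (-62.8) was 15 from Cy3 arrays alone, 2.17 at a score of 15, 21.5 without the rich blocks and 9.67 without the male parent's Cy5 array. It kept its direction but was -2725 from Cy5 arrays alone, -1700 with no requirement on single orientations, -141.0 with normexp, -106.0 with loess, -22.3 at a score of 8, -37.2 with at least 10 probes and -35.8 with the probe filter. It was -68.3 to -45.0 under the other alternatives and -69.5 to -55.1 with each progeny left out; its exact permutation p stayed between 0.0714 and 0.821.

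Windows that differ between progeny and parents (43) became 1367 from Cy5 arrays and 0 from Cy3 arrays alone, 1338 and 0 with windows of 5 and 20 probes, 1199 with no minimum difference, 0 with the parents as 1 group, 0 without the rich blocks, and 7 without the male parent's Cy5 array, of which 6 were lower in progeny. The limma counts of 0 came with 6948, 6423, 8916 and 7656 windows at an unadjusted p under 0.05. Each progeny left out gave 39 to 43. Windows that differ from the reference mouse (6) became 1 with loess, 29 from Cy5 and 10 from Cy3 arrays alone, 1 and 3 with windows of 5 and 20 probes, 23 with no minimum, 0 with the parents as 1 group, and 0 to 7 with each progeny left out. Of 176 values of the 22 named regions under 8 alternatives, 174 kept their direction, 154 stayed within their SD and 20 moved further. This SD is the spread between the dye-swapped arrays of the mouse. The alternatives include each dye orientation alone. Such values lie within the SD by construction and keep their direction by the rule for calls, so they do not test stability. Where the arrays disagree the SD is wide, as for the chromosome 10 loss in progeny 6 (-0.38 on Cy5, -1.75 on Cy3). With probes well above background, the loss on chromosome 3 from 95374904 in progeny 6 turned to 0.033 and that on chromosome 1 from 106041489 in progeny 5 to 0.043. The chromosome 13 loss stayed between -0.48 and -0.41 and the chromosome 4 gain in progeny 5 between 0.48 and 0.58. Median signal over background was between 2.66 and 5.91 for Cy5 and between 4.89 and 9.30 for Cy3, with the highest values in progeny 5 and 6. No paired analysis was possible because each parent is a single animal and all progeny belong to the same family. The planned test of gene lists was not run.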

Other observations

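The test in this part was set before its values were seen, on a pattern already noticed.

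At 24 regions on 14 chromosomes a loss was carried by exactly progeny 5 and 6, against 1 region in the background. These mice have the least noisy arrays and are also the only ones scanned in the fourth session, so an effect of that session common to both dye orientations, which the sign-turned background cannot hold, stays open. A candidate explanation is that these are the same losses as in the female parent and progeny 4, below the threshold there. Over the 24 regions the median log2 ratio was -0.13 in the female parent and -0.19 in progeny 4, both below the medians of the male parent at 0.04 and of progeny 1, 2 and 3 at -0.02, -0.03 and -0.07. Below 0 were 20 of the regions in the female parent and 22 in progeny 4, and 6, 18, 15 and 19 in the male parent and progeny 1, 2 and 3. Below -0.15 were 10 in the female parent and 17 in progeny 4, and 1, 3, 1 and 7 in the male parent and progeny 1, 2 and 3.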
